A study of Escherichia coli K-12 with 16 samples.

How the data were processed

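The 16 RNA-seq libraries of *Escherichia coli* K-12 MG1655 (rph+) comprised 2 for each of 8 groups made of 4 strains with or without azidothymidine (AZT). Per the labels, cultures grew in LB (Lennox) at 37 °C to an optical density of 0.3, were split, and received 100 ng/ml AZT or nothing for 1 hour. RNA was extracted with a column kit, depleted of rRNA and made into libraries with unique molecular identifiers for the removal of PCR duplicates, per the labels. Spike-in RNAs were added, per the labels, but the table used here has 0 rows that name them, so scaling to spike-ins was not run. The genotype labels of lexA3 replicate 1, treated and untreated, also list a kan marker that those of replicate 2 leave out, and whether these were the same strain is not given in the sources used here.

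The deposited table holds raw whole-number counts per gene and library, which the authors had not normalized. Per the submitters' processing notes cutadapt, STAR, DESeq2 and edgeR were used. Their roles and versions, the program that counted the reads, the strand setting and the genome build are not given in the sources used here. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. A second deposited table of normalized values has a single pooled value per group and was not used. Because no build is named, no coordinates are printed. A reference gene table (ASM584v2) served only for names and gene order. Of 4419 rows, 4414 locus tags matched it, 5 did not, and 119 symbols differed. Genes are given by the symbol and b-number of the count table.

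Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. The 22 rRNA rows were left out of the library sizes and tests, since near-identical copies share reads. After filterByExpr, 4089 genes remained and 308 were removed. TMM factors scaled the libraries, and a quasi-likelihood model with 8 group means, fitted to all 16 libraries (8 residual degrees of freedom), gave log2 fold changes and p-values. The common dispersion was 0.00615. Benjamini-Hochberg adjustment was applied within each of 12 comparisons at 0.05. The standard error (SE) of a fold change was its size divided by the square root of its F statistic. CPM values used TMM-scaled library sizes and are given as mean ± SD of 2 libraries. Totals ran from 5604298 to 12629786 counts, and the replicates of a group correlated across genes at 0.991 to 0.996 (log2 CPM).

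Before the data were examined, the tests, the 12 comparisons, 27 gene lists, the alternatives and the rule for named genes were fixed. Lists were tested with camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 27 lists of a comparison. A list count gives members past the gene test, adjusted over all genes unless "adjusted over the list alone" is written. By the naming rule, the 8 genes with the largest rise and the 8 with the largest fall were taken in each of 7 main comparisons, and 5 and 5 in the others. They had to pass the test, have a mean of at least 10 CPM, and show both libraries of a group beyond both of the other. lexA, sspA, sspB, malG and 8 SOS genes were added in each comparison, as were up to 4 leading members of each called list. Some of these names are left out of the text.

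The trend along the chromosome used the order of genes in the reference table as distance from the origin, placed between mnmG and mioC, since coordinates of the authors' build were not given. The plan had made this test depend on such coordinates, so gene order is a departure from it. The slope of log2 CPM was computed per library and compared by an exact permutation of treatment labels within strains. Medians were also taken over 5 equal parts of that distance, for all genes tested that had a place in the order, and the slope was computed again within the middle 3 parts, a test chosen after the medians had been seen. Pyrimidine, ribosomal protein and ymg gene patterns were examined further after their values had been seen.

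The scripts were tested on simulated data. In counts drawn from the real means and library sizes for the AZT comparison in wild type, with 4062 genes tested, 44.9% of seeded genes with a true log2 change of 0.5 were called in the right direction, 81.6% at 1, and 98.0% at 2 and at 3. Of the 168 calls, 4.76% were unchanged genes. A seeded list of genes was called and 0 of 26 random lists were. Each gene was drawn independently there, so this does not test lists of genes that vary together. An added slope of -0.5 along the chromosome was recovered as -0.49.

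Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, rRNA rows kept, a robust fit, a fit of the compared groups alone, a replicate block, a block by culture, and leaving out each library. When a library was left out, the remaining sample of its group was assumed to vary like the others. Figures were drawn with matplotlib in Python.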

Results

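RNA was sequenced from 4 strains of *Escherichia coli* K-12 MG1655, each grown with or without azidothymidine (AZT), a thymidine analogue that ends DNA chains when it is built into them. The strains were an rph+ wild type, a lexA3 mutant, an sspA deletion mutant and a lexA3 sspA double mutant. LexA is the repressor of the SOS DNA damage regulon, and the lexA3 allele encodes a form that resists cleavage. SspA is the stringent starvation protein, which binds RNA polymerase. Both lexA3 strains also carried a Tn10 insertion in malG, so that lexA3 and this insertion always occurred together. Each of the 8 groups had 2 libraries, 16 in all. Total counts per library ranged from 5604298 to 12629786 over 4419 genes. The labels call the libraries of a group biological replicates without saying that they came from separate cultures. The p-values therefore reflect the spread between these samples, estimated for each gene over all 8 groups together. That spread was uneven. Between the libraries of a group, the chi-square of gene counts per degree of freedom ran from 4.59 in untreated wild type to 57.9 in the untreated sspA mutant.

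The engineered genes were examined first. The sspA gene (b3229) had 279 ± 3.0 CPM (counts scaled to the library size; mean ± SD, n = 2) in untreated wild type and 16.2 ± 0.23 in the untreated sspA mutant, a log2 fold change of -4.11 ± 0.11 (SE). In the untreated double mutant it had 21.2 ± 0.073 CPM, and the change against lexA3 was -3.60 ± 0.10. The next gene, sspB (b3228), was also lower in the sspA mutant than in wild type, by -1.24 ± 0.14 on the log2 scale. malG (b4032) had 50.0 ± 5.2 CPM in untreated wild type and 0.435 ± 0.16 in untreated lexA3, a change of -6.75 ± 0.25. The lexA3 allele is a point change and cannot be checked from counts per gene.

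The first comparison asked how wild-type cells responded to AZT. The SOS regulon rose: 30 of its 36 measured genes were higher and 3 lower, with a median log2 fold change of 1.70 (camera adjusted p = 4.95e-09, and adjusted p = 0.00281 with an estimated correlation). Adjusted over the list alone, 30 were higher and 4 lower. tisB (b4618), which encodes a membrane toxin, rose by 6.14 ± 0.18, and umuD (b1183), a subunit of the translesion polymerase, by 5.76 ± 0.13. The division inhibitor gene sulA (b0958) went from 48.6 ± 1.4 to 934 ± 20 CPM, a log2 fold change of 4.26 ± 0.12. recA (b2699), the recombinase that triggers LexA cleavage, went from 659 ± 3.7 to 4889 ± 70 CPM, a change of 2.89 ± 0.14. The lexA gene itself (b4043) rose by 0.77 ± 0.09. The e14 prophage genes rose as well (16 of 19, median 4.45), led by ymfT (b1146) at 6.56 ± 0.13 and ymfL (b1147) at 6.49 ± 0.15, although the call of this list was lost with an estimated correlation (adjusted p = 0.0686).

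Outside the SOS genes, the RpoS general stress, flagellar and maltose lists fell in wild type after AZT. Growth state at harvest was not measured here. For these lists and those below, it cannot be told apart from the drug. Of 40 genes of the RpoS general stress list, 38 fell and 2 rose (median -1.69, adjusted p = 4.69e-10, and adjusted p = 0.00281 with an estimated correlation). Examples were osmB (b1283) at -3.97 ± 0.12 and the DNA-protecting protein gene dps (b0812) at -3.33 ± 0.13. Of 47 flagellar and chemotaxis genes, 36 fell and none of the others passed the test (median -1.91, adjusted p = 1.98e-07, and adjusted p = 0.00710 with an estimated correlation). All 11 maltose genes fell (median -4.44), with malK (b4035) going from 590 ± 14 to 9.39 ± 0.043 CPM, but the list's call was lost with an estimated correlation (adjusted p = 0.0686). Heat shock genes, in contrast, rose in 12 of 20 cases and fell in 2 (median 0.72, adjusted p = 0.0143), a call lost with an estimated correlation (adjusted p = 0.488). Large single falls were also seen for trpE (b1264), of tryptophan synthesis, at -5.59 ± 0.18 and the outer membrane protease gene ompT (b0565) at -4.80 ± 0.18.

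Ribosomal protein, iron acquisition and dNTP supply genes rose in wild type. Of 53 ribosomal protein genes, 45 rose and 2 fell (median 1.10, adjusted p = 2.38e-09). This call was lost with an estimated correlation (adjusted p = 0.273). rplD (b3319) went from 65.1 ± 4.9 to 601 ± 3.4 CPM. In the same libraries the share of counts on rRNA genes, which the tests left out, was 2.12 ± 0.27% without and 3.20 ± 0.24% with AZT. Iron acquisition genes rose (34 of 41, median 1.26), among them fepA (b0584) at 3.82 ± 0.14, with adjusted p = 1.84e-08 and adjusted p = 0.0686 with an estimated correlation. Against the list, its members feoA and feoB fell at least 2-fold in wild type and in each other strain. The ribonucleotide reductase and dNTP supply list rose in 13 of 21 genes (median 0.80, adjusted p = 0.00310, and adjusted p = 0.183 with an estimated correlation). Its leading gene nrdA (b2234), the large subunit of the reductase, rose by 3.72 ± 0.12. carA (b0032), the first gene of pyrimidine and arginine precursor synthesis, went from 9.72 ± 1.5 to 888 ± 74 CPM, a change of 6.50 ± 0.15. The purine and pyrimidine synthesis list to which it belongs was not called, with 11 of 25 genes higher and 12 lower (adjusted p = 0.725). Over all genes, 2810 of 4089 passed the quasi-likelihood test at an adjusted p of 0.05, 1358 higher and 1452 lower, and 690 and 777 of them changed at least 2-fold.

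**Figure D1:**
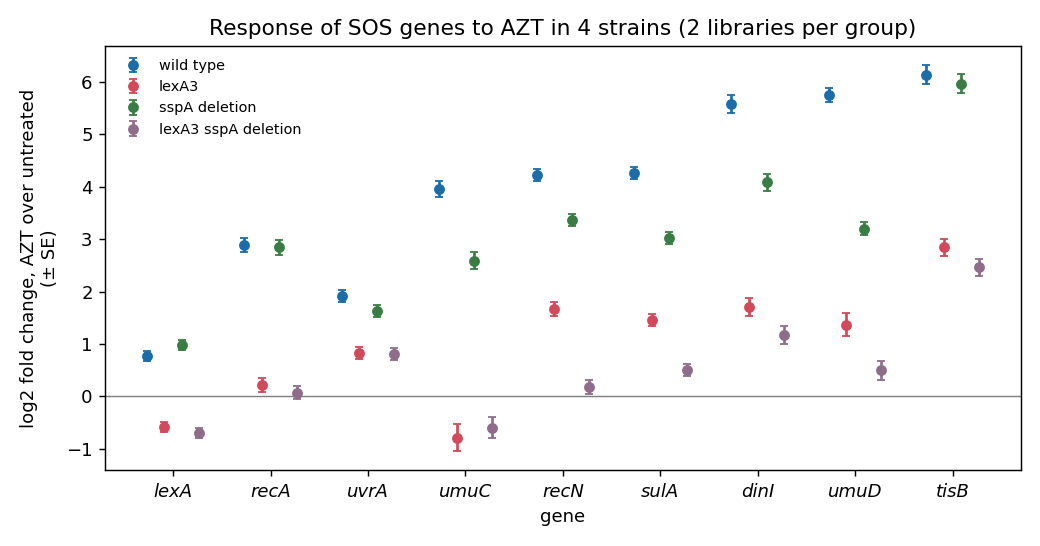
Log2 fold change with AZT (vertical axis, ± SE) of 9 SOS genes (horizontal axis) in the 4 strains, each from 2 treated and 2 untreated libraries. recA lies at 2.89 in wild type and 2.85 in the sspA mutant, against 0.21 in lexA3 and 0.07 in the double mutant.

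The lexA3 strain was treated in the same way to measure the response where LexA cannot be cleaved. The SOS list rose less in this strain: 18 of 36 genes were higher and 6 lower (median 0.48, adjusted p = 0.0137). That call was lost with an estimated correlation (adjusted p = 0.157). Adjusted over the list alone, the counts were again 18 and 6. recA had a change of 0.21 ± 0.13, which did not pass the test, sulA rose by 1.46 ± 0.12 and tisB by 2.84 ± 0.17. The highest rises were in a cluster of small genes beside the e14 prophage: ymgC (b1167) rose by 7.76 ± 0.17, ariR (b1166) by 6.63 ± 0.17 and iraM (b1160) by 6.03 ± 0.17. Flagellar genes fell in 44 of 47 cases (median -2.83, adjusted p = 5.84e-11, and adjusted p = 0.00393 with an estimated correlation), with fliA (b1922), the flagellar sigma factor, at -4.72 ± 0.24. RpoS genes fell in 32 of 40 cases (median -1.17, adjusted p = 2.63e-05, and adjusted p = 0.0274 with an estimated correlation). Purine and pyrimidine synthesis genes fell in 15 of 25 cases and rose in 6 (median -1.17, adjusted p = 0.0143), a call lost with an estimated correlation (adjusted p = 0.422). Within it pyrB (b4245) fell by 3.45 ± 0.14 and carA rose by 2.40 ± 0.12. The maltose list fell (median -2.39) with adjusted p = 3.70e-05, and adjusted p = 0.219 with an estimated correlation. In all, 2904 genes passed the test, 1412 higher and 1492 lower, of which 639 and 784 changed at least 2-fold.

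The difference between the AZT responses of lexA3 and wild type was tested directly. The SOS list responded less in lexA3, with 27 of 36 genes lower and 2 higher (median difference -1.26, adjusted p = 1.21e-10, and adjusted p = 0.00227 with an estimated correlation). recA differed by -2.68 ± 0.19, sulA by -2.80 ± 0.16 and umuD by -4.39 ± 0.31. The e14 list differed in the same direction in 15 of 19 genes (median -2.82, adjusted p = 5.20e-09, and adjusted p = 0.0914 with an estimated correlation). Ribosomal protein genes also responded less in lexA3 (37 of 53, median -1.02, adjusted p = 4.17e-13), which was lost with an estimated correlation (adjusted p = 0.164). These genes already stood higher in untreated lexA3 than in untreated wild type, a list call also lost with an estimated correlation. osmB, which fell in wild type, differed by 4.72 ± 0.16, and pyrB, which rose there, by -5.52 ± 0.19. The RpoS general stress list, with osmB among its leading members, was also called for this difference. That call was lost with an estimated correlation. Responses differed for 1694 genes, 860 higher and 834 lower in lexA3, and 240 of them had passed the test in opposite directions in the 2 strains.

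AZT treatment of the sspA mutant gave the response without SspA. Here the SOS list rose in 26 of 36 genes and fell in 3 (median 1.54, adjusted p = 2.18e-09, and adjusted p = 0.00169 with an estimated correlation), the same counts as adjusted over the list alone. tisB rose by 5.96 ± 0.18, recA by 2.85 ± 0.14 and sulA by 3.03 ± 0.11, and nrdA rose by 4.30 ± 0.12. Flagellar genes fell in 41 of 47 cases (median -2.05, adjusted p = 8.01e-12, and adjusted p = 0.00169 with an estimated correlation). Of 40 RpoS genes 8 rose and 7 fell, and that list was not called (adjusted p = 0.879). Purine and pyrimidine synthesis fell in 14 of 25 genes (median -0.59, adjusted p = 1.53e-05), a call lost with an estimated correlation (adjusted p = 0.266). Its leading members were the pyrimidine genes pyrB at -7.41 ± 0.22, carB (b0033) at -5.37 ± 0.15 and carA at -4.97 ± 0.15, and the uracil transporter gene uraA (b2497) fell by 4.67 ± 0.11. Heat shock genes fell in 16 of 20 cases (median -0.64, adjusted p = 0.000446, and adjusted p = 0.278 with an estimated correlation), such as dnaK (b0014) at -1.70 ± 0.11. There were 2318 genes past the threshold, 1161 higher and 1157 lower, of which 520 and 443 changed at least 2-fold.

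Compared with the wild-type response, that of the sspA mutant differed for 2016 genes, 1103 higher and 913 lower, and 383 had been called in opposite directions. The largest difference was for carA (-11.46 ± 0.21): its mean CPM went from 9.72 to 888 in wild type and from 430 ± 65 to 13.8 ± 0.51 in the mutant. pyrB differed by -9.48 ± 0.26 and uraA by -7.15 ± 0.15. RpoS genes responded more positively in the mutant (34 of 40, median 1.81, adjusted p = 3.13e-11, and adjusted p = 0.00422 with an estimated correlation), for example dps at 3.07 ± 0.17. All genes of that list were already lower in the untreated mutant than in untreated wild type. The list was not called with AZT in the mutant itself, so the difference came mostly from the fall in wild type. The RpoS list was also called, in the same direction, for lexA3 against wild type, a call lost with an estimated correlation. The difference may therefore not be particular to the sspA mutant. Iron genes responded less (34 of 41, median -1.60, adjusted p = 1.43e-13, and adjusted p = 0.0499 with an estimated correlation), for example the enterobactin esterase gene fes (b0585) at -5.00 ± 0.27. Its mean CPM went from 2.03 to 31.8 in wild type and from 31.1 to 15.5 in the mutant. Iron genes were already higher in the untreated mutant, a list call lost with an estimated correlation. The SOS list did not pass as a whole (median -0.20, adjusted p = 0.171, with 10 genes lower and 6 higher). Single SOS genes did: sulA differed by -1.24 ± 0.15 and umuD by -2.56 ± 0.21. In the other direction, uvrD (b3813) rose by 1.05 ± 0.11 in wild type and by 2.85 ± 0.12 in the sspA mutant.

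**Figure D2:**
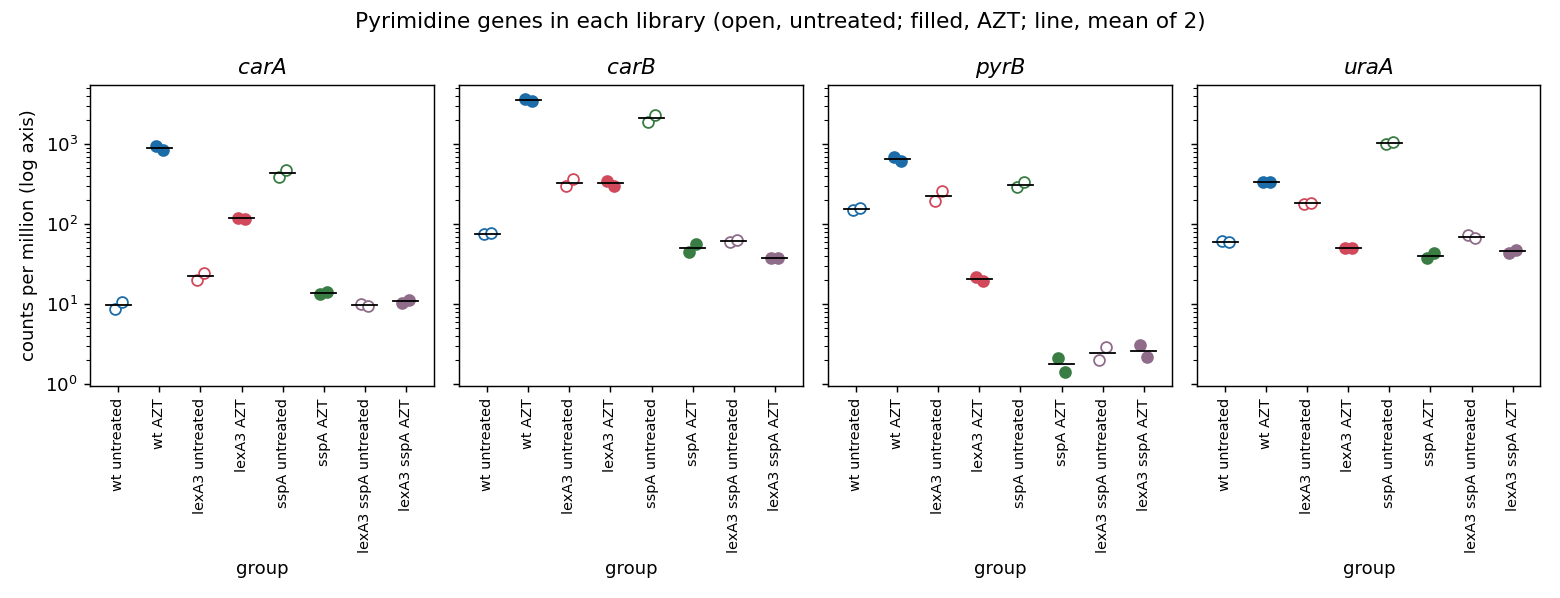
CPM (log axis) of carA, carB, pyrB and uraA in each of the 16 libraries by group, open for untreated and filled for AZT, with a line at the mean of 2 libraries. carA stands at 888 in treated and 9.72 in untreated wild type, and at 13.8 in treated and 430 in untreated sspA mutant cells.

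In the double mutant, AZT left the SOS list without a call (15 of 36 genes higher, 8 lower, median 0.24, adjusted p = 0.151). tisB rose by 2.46 ± 0.17 and sulA by 0.50 ± 0.12. Flagellar genes fell in 37 of 47 cases (median -1.83, adjusted p = 2.59e-09, and adjusted p = 0.00690 with an estimated correlation). nrdA rose by 3.56 ± 0.12 and ymgC by 5.04 ± 0.13. The acid resistance list rose (8 of 14, median 1.14, adjusted p = 0.00876, and adjusted p = 0.123 with an estimated correlation), led by its regulator gadE (b3512), which went from 3.66 ± 0.57 to 38.5 ± 0.50 CPM. The purine and pyrimidine synthesis list was not called (7 of 25 higher, 4 lower, adjusted p = 0.565), and pyrB had 2.50 ± 0.66 CPM without and 2.65 ± 0.65 with AZT. In total 2516 genes passed, 1248 higher and 1268 lower, and 418 and 477 of these changed at least 2-fold.

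Against the sspA single mutant, the double mutant's response was lower for SOS genes (26 of 36, median difference -1.39, adjusted p = 1.90e-14, and adjusted p = 0.000632 with an estimated correlation), with recA at -2.77 ± 0.19 and tisB at -3.50 ± 0.23. Purine and pyrimidine synthesis genes responded more positively (18 of 25, none lower, median 1.08, adjusted p = 2.19e-12, and adjusted p = 0.0917 with an estimated correlation), with pyrB at 7.40 ± 0.47 and carA at 5.13 ± 0.23. The same test gave 1104 genes, 485 higher and 619 lower. Set against lexA3, the double mutant's response differed for 1730 genes, 942 higher and 788 lower. RpoS genes accounted for a part of these (35 of 40 higher, median 1.22, adjusted p = 1.53e-11, and adjusted p = 0.00348 with an estimated correlation), with wrbA (b1004) at 1.45 ± 0.17.

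Without AZT, lexA3 was compared with wild type to see the state of the strain before treatment. SOS genes were lower in lexA3 (29 of 36, with 1 higher, median -0.70, adjusted p = 7.80e-08, and adjusted p = 0.00697 with an estimated correlation), for example recN (b2616) at -2.57 ± 0.13 and tisB at -1.93 ± 0.17. Ribosomal protein genes were higher in 50 of 53 cases (median 1.74, adjusted p = 3.83e-27), and that call was lost with an estimated correlation (adjusted p = 0.0555). Genes of the S10 operon led: rplD stood at 65.1 ± 4.9 CPM in wild type and 959 ± 188 in lexA3, and rpsJ (b3321) was higher by 3.73 ± 0.15. The share of counts on rRNA genes was 2.12 ± 0.27% in untreated wild type and 1.01 ± 0.12% in untreated lexA3. Flagellar genes were higher (30 of 47, median 0.75, adjusted p = 1.05e-06, and adjusted p = 0.0144 with an estimated correlation), with the flagellin gene fliC (b1923) at 2.74 ± 0.17. Iron acquisition genes were higher in 32 of 41 cases (median 0.76, adjusted p = 9.31e-11, and adjusted p = 0.0555 with an estimated correlation). The gene test called 2056 genes, 1004 higher and 1052 lower, 234 and 308 of them by at least 2-fold.

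The untreated sspA mutant, in which sspB was lower too, was compared with wild type in the same way. All 40 RpoS genes were lower (median -1.48, adjusted p = 2.32e-14, and adjusted p = 0.00160 with an estimated correlation). Acid resistance genes were lower in 13 of 14 cases (median -2.66, adjusted p = 7.62e-07, and adjusted p = 0.00477 with an estimated correlation), with gadE at -4.05 ± 0.16 and the periplasmic chaperone gene hdeB (b3509) at -3.96 ± 0.15. Flagellar genes were higher (39 of 47, median 1.26, adjusted p = 5.38e-09, and adjusted p = 0.00466 with an estimated correlation). Heat shock genes were higher in 16 of 20 cases (median 1.35, adjusted p = 9.36e-07, and adjusted p = 0.118 with an estimated correlation), with dnaK at 2.33 ± 0.12. Iron acquisition genes were higher in 33 of 41 cases (median 1.35, adjusted p = 3.16e-09, and adjusted p = 0.0607 with an estimated correlation), with fes at 3.96 ± 0.21. Ribosomal protein genes were higher in 38 of 53 cases and lower in 6 (median 0.69, adjusted p = 7.48e-06, and adjusted p = 0.399 with an estimated correlation). Among single genes, carA was higher by 5.45 ± 0.15 and trpE lower at -7.51 ± 0.22. Several of these differences were not particular to the sspA mutant. The flagellar, iron acquisition and ribosomal protein lists were also higher in untreated lexA3, against the same wild-type libraries. The RpoS list was called in untreated lexA3 too, a call lost with an estimated correlation. In the untreated double mutant all 40 RpoS genes were lower as well. trpE was also among the largest falls in untreated lexA3 and in the untreated double mutant. The test called 2335 genes, 1155 higher and 1180 lower, 412 and 492 of them by at least 2-fold.

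The untreated double mutant was set against wild type and against lexA3. Against wild type, all 53 ribosomal protein genes were higher (median 1.82, adjusted p = 1.17e-18, and adjusted p = 0.0710 with an estimated correlation), and the share of counts on rRNA genes was 1.18 ± 0.047%. Iron acquisition genes were higher in 32 of 41 cases (median 1.39, adjusted p = 9.78e-10, and adjusted p = 0.0555 with an estimated correlation). All 40 RpoS genes were lower (median -2.04, adjusted p = 4.51e-17, and adjusted p = 0.000906 with an estimated correlation). Purine and pyrimidine synthesis genes were lower in 19 of 25 cases (median -1.68, adjusted p = 3.15e-08, and adjusted p = 0.0710 with an estimated correlation), with purH (b4006) at -5.10 ± 0.17 and pyrB at -5.86 ± 0.19. This comparison gave 2550 genes, 1291 higher and 1259 lower. Against lexA3, the acid resistance list was lower in 12 of 14 cases (median -2.69, adjusted p = 3.85e-06, and adjusted p = 0.0101 with an estimated correlation), the tryptophanase gene tnaA (b3708) changed by -5.51 ± 0.14, and 2566 genes passed, 1309 higher and 1257 lower. In addition, 7 lists, among them recombination and repair outside SOS and cell division, passed in none of the 12 comparisons. Not every called list is described in the text. Replication machinery was called in the 4 AZT comparisons, calls lost with an estimated correlation. Also left out were anaerobic respiration and fermentation and carbon uptake under CRP (7 comparisons each). Others were other cryptic prophages and the TCA cycle (6 each) and branched-chain amino acid synthesis (5).

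**Figure D3:**
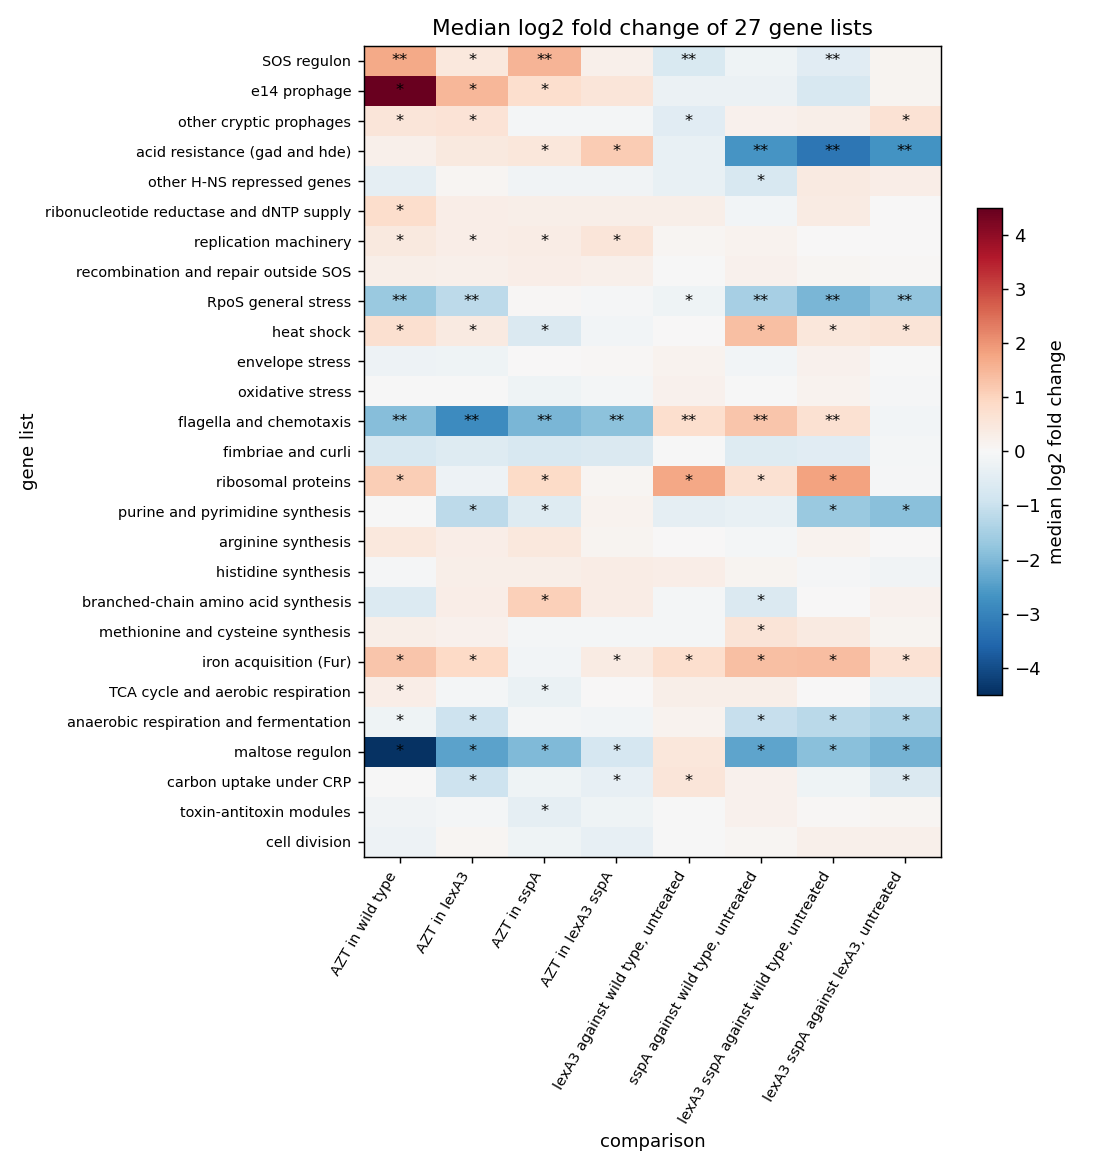
Median log2 fold change (colour) of the 27 gene lists (rows) in the 4 AZT comparisons and the 4 untreated strain comparisons (columns). A star marks lists called with the preset correlation and a pair of stars those also called with an estimated one. The flagellar list carries a pair of stars in all 4 AZT columns, with medians from -2.83 to -1.83.

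The 4 AZT responses rest on separate libraries and were compared across genes, which are not independent replicates. Pearson's r over 4089 genes was 0.73 between wild type and lexA3 and 0.73 between the sspA and double mutants, 0.72 between lexA3 and the double mutant, and 0.51 to 0.58 for the other pairs, lowest between wild type and the sspA mutant. Wild type and lexA3 shared 942 higher genes, where 469 would be shared by independent lists, and 1060 lower genes against 530. In all 4 strains, 452 genes were called higher and 541 lower, 127 and 177 of them at least 2-fold.

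Expression was also described along the chromosome, by gene order from the replication origin to the terminus, for 3959 protein-coding genes. The slope of log2 CPM over that distance was more negative with AZT in each strain, by -0.39 in wild type, -0.64 in lexA3, -0.78 in the sspA mutant and -0.82 in the double mutant. The mean change was -0.66 (exact permutation test within strains, two-sided p = 0.00154, the smallest that the 1296 arrangements can give). Medians by part were not alike between strains, a difference that was not tested. With the arm divided into 5 equal parts, the median log2 fold change of the part nearest the terminus was -0.40 in wild type and -0.58 in lexA3, and that of the part nearest the origin 0.076 and 0.095. In the sspA mutant the part nearest the origin stood at 0.54 and that nearest the terminus at -0.20, and in the double mutant at 0.40 and -0.37.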

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

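The tests of exchanged labels, growth state, the malG insertion, copy number and LexA cleavage were chosen after the results had been seen, and the test of sequencing depth was fixed before its value was computed.

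Differences between the strains in the response to AZT were each found by a test of the difference itself, with values as log2 differences. Between lexA3 and wild type 1694 genes differed, among them osmB (4.72), recA (-2.68), sulA (-2.80), umuD (-4.39) and pyrB (-5.52), and the SOS list had a median difference of -1.26. The RpoS list was called there too, a call lost with an estimated correlation. Between the sspA mutant and wild type 2016 genes differed, among them carA (-11.46), pyrB (-9.48), uraA (-7.15), fes (-5.00), dps (3.07), sulA (-1.24) and umuD (-2.56), with list medians of 1.81 for RpoS genes and -1.60 for iron genes. The double mutant differed from lexA3 for 1730 genes, among them wrbA (1.45), with a median of 1.22 for the RpoS list. It differed from the sspA mutant for 1104 genes, among them recA (-2.77), tisB (-3.50), carA (5.13) and pyrB (7.40), with a median of -1.39 for the SOS list.

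The rRNA genes, which no comparison used, took a larger share of counts in treated than in untreated libraries of each strain. The treated means were 3.20%, 4.05%, 2.67% and 3.07% in wild type, lexA3, the sspA mutant and the double mutant, and the untreated means were 2.12%, 1.01%, 1.97% and 1.18%. The mean difference was 1.68 percentage points (exact permutation within strains, two-sided p = 0.00154, the smallest possible). How far rRNA was depleted in each library was not measured.

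The pyrimidine genes carA, carB, pyrB and uraA rose with AZT in wild type and fell in the sspA mutant. In lexA3 carA rose (2.40), pyrB (-3.45) and uraA (-1.85) fell and carB (-0.040) was not called, and in the double mutant carB (-0.71) and uraA (-0.59) fell and carA (0.16) and pyrB (-0.0075) were not called. Exchanged strains are argued against by sspA, whose lowest CPM in a wild-type library was 12.9 times the highest in an sspA mutant library, and exchanged treatments by sulA, whose lowest treated CPM was at least 7.37 times the highest untreated one in both strains. The pyrimidine supply or growth state of the cultures cannot be told apart from strain and drug, since no batch is recorded, and libraries of a group differed by at most 0.309 for carA (log2). An effect of the sspA deletion stays open, with falls of pyrB and uraA also in lexA3, which has the gene, and with an untreated pyrB level of only 2.50 CPM in the double mutant, which lacks it.

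Ribosomal protein genes were higher in untreated lexA3 than in wild type, a call lost with an estimated correlation (adjusted p = 0.0555). After each library was thinned to the smallest total, the list median was 1.70. Thinning keeps each gene's expected share of counts, so this outcome was nearly fixed for abundant genes. It is not counted for or against greater depth of the lexA3 libraries. The malG insertion, or another difference of the lexA3 strains, cannot be told apart from the lexA3 allele, because both lexA3 strains carry both; the double mutant had a list median of 1.82 against wild type (adjusted p = 0.0710 with an estimated correlation). The list was also higher in the sspA mutant, which has neither (median 0.69, adjusted p = 0.399 with an estimated correlation), so that all 3 mutants stood above the same 2 wild-type libraries. The state of those wild-type cultures, and the growth state of the others, was not tested and stays open.

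The genes ycgZ, ymgA, ariR, ymgC and iraM, singled out after their values were seen, rose with AZT in all 4 strains, with medians from 4.23 to 6.03. A gain in copy number of the region is argued against by the 12 neighbouring genes tested, whose median was at most 0.75 in any strain, although ymgK, ymgL and ycgX among them rose in all 4 strains. A need for LexA cleavage is argued against by the median difference between lexA3 and wild type, 0.806 towards lexA3. A response that does not need LexA cleavage stays as a hypothesis, and what regulates it was not tested.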

How the results depend on the processing

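No alternative setting was added after the data had been seen. Across 156 alternative fits of the 12 comparisons, counts of called genes stayed between 0.737 and 1.13 times the reported counts. Both extremes came from leaving out a library. DESeq2 gave 0.857 to 0.940 times the reported counts, and another scaling (RLE) 0.996 to 1.01. Which of higher and lower calls was the larger turned in 31 of these fits. Of these, 12 used RLE or DESeq2, whose scaling moves the centre of all fold changes and so is no test of the balance, and the other 19 fell in 7 of the 12 comparisons. For the sspA response against wild type (1103 higher, 913 lower) the counts were 1020 and 1007 with RLE, and 959 and 968 without untreated sspA replicate 2. Without the same library the double mutant against sspA (485 higher, 619 lower) gave 518 and 482. Pairing of the samples by replicate number was not shown, nor was it excluded. Deviations of treated and untreated libraries with the same number correlated at -0.036 in wild type and 0.112 in lexA3. The values were 0.048 in the sspA mutant and -0.0089 in the double mutant. Low correlations cannot tell whether a number marks the same split culture. With the replicate block, AZT in wild type gave 2813 genes and lexA3 against wild type 2058, with counts 0.994 to 1.00 times those reported over the comparisons. A block by culture raised all 8 counts it was fitted for, to between 1.01 times (AZT in wild type, 2849) and 1.11 times (the double mutant against sspA, 1225). Of 122 list calls, 24 held with an estimated correlation, and 121 with the replicate block. The list of other H-NS repressed genes in the sspA mutant had adjusted p = 0.0499 without and 0.0578 with the block. Beyond the counts, 106 gene values that are named in the text or plotted were refitted in 1322 alternative fits. recA with AZT in the double mutant, which was not called, ranged from -0.055 to 0.18 when each library was left out and was negative without treated replicate 2. umuD in the double mutant (0.50) lost its call with DESeq2 and without either treated library or untreated replicate 2, with values from 0.44 to 0.52 over the libraries left out. umuC, which was lower with AZT in lexA3 (-0.79) and in the double mutant (-0.60), lost its call without treated replicate 1 in lexA3, and without untreated replicate 1 or treated replicate 2 in the double mutant. Changes of sign were also seen for carB in lexA3 (-0.040, not called), at 0.0039 with RLE, 0.0042 with DESeq2 and -0.17 to 0.098 with a library left out. pyrB in the double mutant (-0.0075, not called) was 0.0031 with RLE, 0.0045 with DESeq2, 0.0066 with the replicate block and -0.27 to 0.37 with a library left out. The cause was not tested for these, apart from the fewer samples of a fit with a library left out. The other gene values kept their direction and their side of the threshold, and the replicate block changed no gene's call. Overlaps of AZT responses were 1.66 to 2.34 times those of independent lists, and 2.56 to 5.28 times for calls of at least 2-fold. The change of slope along the chromosome was -0.66, -0.45 among genes with a mean of at least 50 CPM and -0.71 without SOS and prophage genes; with the replicate block the exact p was 0.00781, the smallest that 256 sign flips allow. Scaling to spike-ins was not run. In simulated counts 44.9% of genes with a true log2 change of 0.5 were called for AZT in wild type. That simulation had only 168 calls, where the real comparison had 2810. With more calls the adjusted threshold is less strict, so this share does not carry over to the real comparison.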

Other observations

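Among 127 genes at least 2-fold higher with AZT in all 4 strains, chosen after their values were seen, were nrdA and cdgI. Their mean log2 fold changes over the strains were 3.83 and 3.31. Among 177 genes at least 2-fold lower, ompT, an outer membrane protease gene, had a mean of -4.13 and the flagellar sigma factor gene fliA a mean of -4.11.

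The tests of the shared displacement and of an even gradient were chosen after the results had been seen, and that of the change of slope was fixed before, although the use of gene order in place of coordinates was chosen later. Genes lower with AZT in wild type were often lower in the untreated sspA mutant too. Both comparisons use the same 2 untreated wild-type libraries, too few to split with 2 in each part. They shared 646 lower genes, where 419 would be shared by independent lists, and 532 higher genes against 384. The covariance of the log2 fold changes was 0.460, against 0.0346 on average in 50 simulations of unchanged groups, a difference of 0.425. Pearson's r was 0.34, against 0.48 in the simulations, where shared controls alone make r high, so the comparison of r decides nothing. The simulations drew each library separately, so a state common to both untreated wild-type libraries could also raise the covariance. A partly shared displacement of expression in both conditions is possible, but the overlap may also come from the shared controls.

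A change of gene dosage along the chromosome is a candidate explanation for the steeper slope of expression from origin to terminus. The slope changed by -0.659 on average, in the same direction in all 4 strains. The medians by part were not alike between strains, which was not tested. In wild type and lexA3 the medians changed most in the part nearest the terminus (-0.40 and -0.58), and in the sspA mutant in the part nearest the origin (0.54). A difference between strains was not tested for the slope within the middle 3 of 5 parts, which changed by -0.343 on average. In wild type (-0.483 ± 0.14, SE across genes) and lexA3 (-0.545 ± 0.13) this change lay within 2 SE of that over the whole arm (-0.39 and -0.64). From origin to terminus, the medians of the 5 parts were 0.076, 0.091, 0.053, -0.015 and -0.40 in wild type. In lexA3 they were 0.095, 0.067, 0.12, -0.064 and -0.58. These medians fell mainly in the last part, so an even gradient is not shown in wild type and lexA3. In the sspA mutant (-0.135 ± 0.11) and the double mutant (-0.211 ± 0.092) the change within the middle parts was smaller. It was under 0.5 times that over the whole arm (-0.78 and -0.82) by more than its SE. This argues against an even gradient in the sspA and double mutants. Neighbouring genes are not independent, so these SEs are likely too small. DNA content was not measured, so regulation of genes near the terminus or the origin may give the same slope, and dosage stays a hypothesis.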
